A study of Mus musculus with 4 samples.

How the data were processed

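Single-cell RNA sequencing libraries of whole mouse bone marrow were made with the 10x GEM-X 5' kit (version 3), per the labels. There were 4 libraries, 1 per group, each from cells pooled over 3 to 6 of the 20 mice, so that mice could not be told from one another. The labels pair no samples. The submitters' processing notes name Cell Ranger, with no version, Partek 12.8.2 and build mm10, without the role or the order of the tools.

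The deposited values were UMIs per gene symbol and barcode, not normalized, taken to be expected counts: the authors' matrices hold whole numbers but for fractions in 23 of 32245 symbols (0.0434% of entries above 0), 17 of which belong to more than 1 gene in GENCODE release M21. All 4 libraries list the same symbols. Sums were rounded to whole UMIs for the intervals. The lowest total of any barcode was 500 UMIs, and what lies below it was not used here. H2-Ea, which BALB/c expresses and C57BL/6 does not, is not among the symbols, so a check of host cells by that gene, chosen beforehand, could not be made. Positions of genes are those of GENCODE release M21 or RefSeq on build GRCm38, found by symbol.

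Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. The gene minimum took out 1533, 1209, 658 and 778 barcodes of healthy, SAA_RvE1, SAA_CsA and SAA_CsA_RvE1 (15.9%, 15.0%, 12.5% and 17.6%), whose median share of haemoglobin UMIs was 53.8%, 50.7%, 43.6% and 49.8%. The mitochondrial limit was exceeded by 262, 269, 270 and 253 barcodes. Of the 8019, 6758, 4520 and 3587 barcodes that passed, those with the highest Scrublet scores were removed as doublet-like at a rate of 0.4% per 1000 barcodes: 373, 261, 110 and 78; the automatic threshold of Scrublet would have removed 157, 59, 20 and 15. The cells left had medians of 4191, 4554, 7614 and 6062 UMIs.

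All cells were clustered together, without integration, by the Leiden method at resolution 1.5 with scanpy 1.11.5 on 3000 variable genes, 40 principal components and 15 neighbours; immunoglobulin and T cell receptor segments and mitochondrial, ribosomal protein and sex-linked genes were left out of this step. Clusters were named from marker lists of 18 cell types written before the data were examined. A cluster took the name of the type whose 12 highest markers had the highest mean log2 ratio, with 10 CPM added, to all other cells. At least 3 markers had to be found in it, and no other type could have more markers among its 10 leading genes. Names mean a likeness in RNA. Of 37 clusters 34 were named, in 13 classes, and 3 were not.

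The design fixed 6 comparisons: each SAA library against healthy, SAA_CsA_RvE1 against SAA_CsA, SAA_RvE1 against SAA_CsA, and SAA_CsA_RvE1 against SAA_RvE1. With 1 library per group no test between groups and no count of differing genes was made from cells. Shares of cells carry exact binomial (Clopper-Pearson) intervals, levels exact Poisson intervals, and ratios of levels exact conditional intervals. Levels were UMIs of a gene per 1000000 UMIs of the class (CPM), in classes with at least 100 cells in both libraries. Genes were named in neutrophil-like, monocyte-like, B progenitor-like, T-like and erythroid-like cells, and each list was read in those of these classes fixed for it beforehand; HSPC-like cells were planned too. With too few cells, HSPC-like cells were not compared in any pair, nor T-like cells in pairs with SAA_RvE1, and the lists for stem cell identity and for lymphoid, myeloid and erythroid or megakaryocyte priming were not read. The single healthy library enters 3 of the comparisons.

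Genes named one by one were, per comparison and class, the 2 with the highest and the 2 with the lowest ratio, ranked by the bound of the interval nearest 1, among genes with at least 50 CPM and 20 UMIs in the higher library and a ratio of at least 1.5-fold. A class's own markers, antigen receptor, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, unnamed gene models and, as possible free RNA, genes under 5% of their level in the class where they were highest were left out. Further genes were list members with the highest and lowest ratios in their list, the receptors of resolvin E1 and the targets of cyclosporine. A gene without a UMI in 1 library was set to a floor of 3 UMIs over the class.

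Gene lists, 32 in number with the technical ones, were written before the data were examined. A list's value is the median log2 ratio of its members with a mean of at least 10 CPM, with 0.5 UMI added to each sum, set against 10000 random lists of the same size whose members came from the 200 genes nearest in level. A list is described as higher or lower where its median lay outside the central 95% of its random lists and was at least 0.3 in size; this minimum was set after seeing the data. Of all 387 medians, 193 lay outside their random range and 99 were described. The intervals of medians come from 200 Poisson draws.

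Gene ratios and list medians were tested on simulated counts with the real means and totals, for the ratios with 200 genes changed by a known fold. These counts held Poisson error only. Filters, doublet removal, clustering, the naming of clusters and the closing tests were not simulated. In neutrophil-like cells the interval lay on the right side of 1 for all changed genes (68 at 1.5-fold, 66 at 2-fold, 66 at 4-fold; 32245 genes in each comparison). In T-like cells this held at 1.5-fold for 46 of 68 genes in SAA_CsA against healthy, 38 of 68 in SAA_CsA_RvE1 against healthy and 41 of 68 in SAA_CsA_RvE1 against SAA_CsA, at 2-fold for 60, 61 and 64 of 66, and at 4-fold for 66, 65 and 65 of 66. Of 100 simulated lists of 20 genes at 1.5-fold, all 100 were described in each comparison of neutrophil-like cells, the only class in which lists were simulated. Of 100 unchanged lists, 4, 7, 5, 2, 6 and 3 lay outside their range in SAA_RvE1, SAA_CsA and SAA_CsA_RvE1 against healthy, SAA_CsA_RvE1 against SAA_CsA, SAA_RvE1 against SAA_CsA and SAA_CsA_RvE1 against SAA_RvE1.

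The alternatives fixed beforehand were: for shares, at least 1000 UMIs per cell, no removal of doublet-like cells, resolution 3, each library clustered by itself and erythroid-like cells left out of the denominator; for genes and lists, TMM scaling (edgeR 4.0.16), totals without mitochondrial, ribosomal protein, haemoglobin and antigen receptor genes, at least 1000 UMIs per cell and each cluster of at least 20 cells at the same weight in both libraries; for genes, no removal of doublet-like cells; for lists, no minimum level, 50 CPM, 2 UMIs added and cells thinned to 1000 UMIs. Alternatives chosen after seeing the data were T-like cells with fewer than 5 neutrophil UMIs, cells of 1 sex by Xist or Y-linked UMIs, and shares without the gene minimum. Of the genes that met the rule for the set used in the closing tests, 1 is not reported here and entered no sum or test of the set. TMM scaling moved the log2 ratios of neutrophil-like cells against healthy by 0.15 in SAA_RvE1, 0.24 in SAA_CsA and 0.19 in SAA_CsA_RvE1, of erythroid-like cells by 0.10 in SAA_CsA and 0.14 in SAA_CsA_RvE1, and of T-like cells by -0.14 in both. Further tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.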

Results

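Bone marrow cells of mice with immune-mediated severe aplastic anaemia (SAA) and of healthy mice were profiled by droplet single-cell RNA sequencing of the 5' ends of transcripts. The mice were F1 hybrids of C57BL/6 and BALB/c. SAA was induced by 350 rad of radiation and an injection of C57BL/6 splenocytes, whose T cells attack the marrow of the hybrid host. From day 7 on, SAA mice were given 5 injections of cyclosporine A (CsA, 10 mg/kg), a calcineurin inhibitor that blocks T cell activation, of resolvin E1 (RvE1, 0.00125 mg/kg), a lipid mediator made from eicosapentaenoic acid that helps end inflammation, or of both. Marrow was taken on day 45, and red cells were lysed. Each group was 1 library from pooled mice: 5 for healthy, 3 for SAA_RvE1, 6 for SAA_CsA and 6 for SAA_CsA_RvE1. SAA mice without a drug were not analysed here.

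The libraries held 9659, 8083, 5254 and 4428 barcodes, in the order healthy, SAA_RvE1, SAA_CsA and SAA_CsA_RvE1 used throughout, with 66621560, 57497032, 54532107 and 41682844 UMIs in all and medians of 3442, 3541, 6054 and 4683 UMIs per barcode. Filters left 7646, 6497, 4410 and 3509 cells in 37 clusters, of which 34 could be named as 1 of 13 classes. There were no replicates, so no test between groups was made, and every interval here is a 95% interval that covers counting error only. Intervals of levels, ratios and list medians treat each UMI as independent, so the spread between cells is not in them. Levels are UMIs per 1000000 UMIs of a class (CPM). All 3 comparisons of SAA libraries with healthy share the single healthy library, so a part of any likeness between them may come from it.

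The first question was how the make-up of the marrow differed between the groups 45 days after induction. Neutrophil-like cells made up 38.1% (37.0 to 39.2), 41.4% (40.2 to 42.6), 48.0% (46.5 to 49.5) and 35.2% (33.6 to 36.8) of the kept cells. Erythroid-like cells, what was left of them after lysis, made up 20.4%, 19.8%, 15.1% and 22.3%. B progenitor-like cells made up 14.1% (13.0 to 15.3) of SAA_CsA_RvE1 and 9.87% (9.22 to 10.6) of healthy, with 10.8% and 10.5% in SAA_RvE1 and SAA_CsA. Mature B-like cells were fewest in SAA_CsA, at 4.58% (3.98 to 5.24), against 8.40% (7.78 to 9.04) in healthy, 6.83% in SAA_RvE1 and 7.95% in SAA_CsA_RvE1. T-like cells were fewest in SAA_RvE1, at 1.02% (0.787 to 1.29, 66 cells), against 2.69%, 2.61% and 2.85% in healthy, SAA_CsA and SAA_CsA_RvE1. Stem and progenitor-like (HSPC-like) cells made up 1.30% (1.05 to 1.57, 99 cells) of healthy, 0.831% (0.625 to 1.08, 54 cells) of SAA_RvE1, 0.703% (0.478 to 0.996, 31 cells) of SAA_CsA and 0.513% (0.304 to 0.810, 18 cells) of SAA_CsA_RvE1. Natural killer and innate lymphoid-like cells followed the same order, at 0.589%, 0.308%, 0.159% and 0.114% (45, 20, 7 and 4 cells). When each library was clustered by itself, SAA_CsA and SAA_CsA_RvE1 gave no HSPC-like cluster. Monocyte-like cells made up 6.84%, 8.33%, 8.16% and 6.38%, macrophage-like cells 2.67%, 2.08%, 2.36% and 2.17%, and unnamed clusters 5.19%, 4.96%, 4.44% and 4.56%. Plasmacytoid dendritic-like cells made up 1.74%, 1.85%, 1.07% and 1.34%, neutrophil progenitor-like cells 1.33%, 1.28%, 1.497% and 1.37%, and basophil- and mast-like cells 0.706%, 0.369%, 0.748% and 0.826%.

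**Figure D1:**
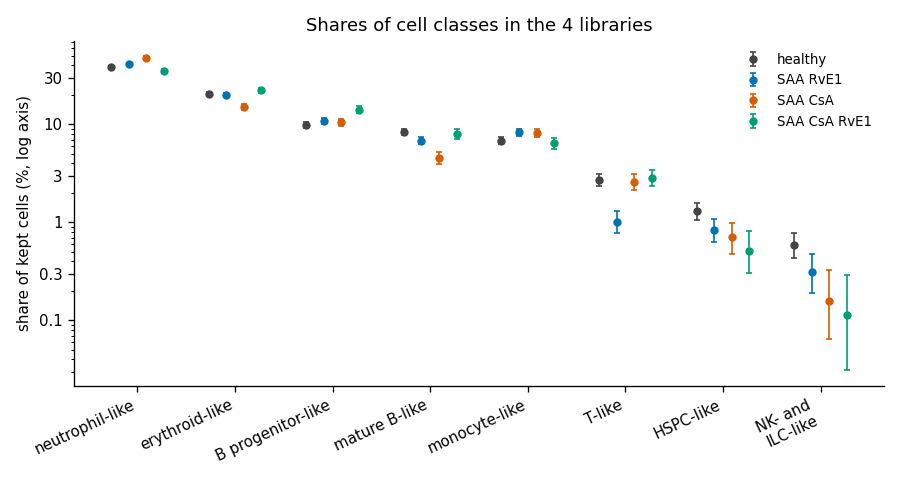
Share of kept cells in each of 8 classes (log axis, %), 1 point per library, bars being 95% binomial intervals of the counting error. HSPC-like cells ran from 1.30% in healthy to 0.513% in SAA_CsA_RvE1, and mature B-like cells were fewest in SAA_CsA at 4.58%.

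SAA_RvE1 against healthy asked how close the marrow came to that of healthy mice when resolvin E1 was the only drug. The pair was alike in most gene groups. In B progenitor-like cells of SAA_RvE1 the genes of MHC class II and of its loading with antigen were higher, among them H2-Aa, H2-Ab1 and Cd74. Immediate-early genes such as Egr1 and Fosb were lower in neutrophil-like and monocyte-like cells, and Cxcl2 and Ptgs2, which drive inflammation, were lower in monocyte-like cells. Thbs1, a matrix glycoprotein, was lower in both myeloid classes, and Ndufa1, an X-linked subunit of respiratory complex I, was lower in myeloid, B progenitor-like and erythroid-like cells.

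In neutrophil-like cells, Wfdc17, a secreted protein of the WAP family, stood at 159.7 v 31.4 CPM (SAA_RvE1 v healthy; ratio 5.09, 4.71 to 5.51) and the cystatin-like gene Cstdc5 at 257 v 92.5 CPM (2.78, 2.65 to 2.92). Thbs1 stood at 29.9 v 128 CPM in these cells (0.233, 0.214 to 0.253) and at 15.0 v 79.6 CPM in monocyte-like cells (0.188, 0.151 to 0.233). Monocyte-like cells also had less Hpgd, the enzyme that inactivates prostaglandins, at 10.3 v 56.8 CPM (0.182, 0.139 to 0.235), and more Tk1, a thymidine kinase of dividing cells, at 97.5 v 65.0 CPM (1.501, 1.33 to 1.70). Ndufa1 (chrX:37187588-37191163, build GRCm38) stood at 54.3 v 155 CPM in neutrophil-like cells (0.350, 0.329 to 0.373), 73.2 v 158 in B progenitor-like cells (0.463, 0.407 to 0.524) and 61.3 v 145 in erythroid-like cells (0.423, 0.384 to 0.466). The heat shock gene Hsph1 in B progenitor-like cells (44.9 v 96.2 CPM; 0.467, 0.396 to 0.548) and the ubiquitin-conjugating gene Ube2k in erythroid-like cells (84.1 v 145 CPM; 0.579, 0.531 to 0.630) were the other named genes.

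Of 56 list medians in this comparison, 1 was higher and 3 were lower than matched random lists by at least 0.3 log2, and the other 52 lay between -0.30 and 0.20. Of those 4, 2 came under 0.3 with TMM scaling and 1 with the clusters at the same weight. MHC class II genes had a median log2 ratio of 0.39 (0.20 to 0.49) in B progenitor-like cells, with 6 of 7 genes higher and H2-Aa at 175 v 121 CPM (ratio 1.45); in cells with a Y-linked UMI alone this median was -0.24. The early response list, which also answers to tissue handling, stood at -0.47 in neutrophil-like cells (17 of 17 genes lower, Egr1 50.2 v 106 CPM, ratio 0.474) and -0.32 in monocyte-like cells (20 of 21 lower). NF-kB and inflammatory cytokine genes stood at -0.34 in monocyte-like cells, with Cxcl2 at 12.1 v 33.4 CPM (0.361) and Ptgs2 at 0.491 of healthy, while Ccl3 was higher (57.4 v 45.2 CPM). Interferon gamma genes were near 0 in each class, at -0.07 in neutrophil-like, 0.03 in monocyte-like, 0.02 in B progenitor-like and 0.01 in erythroid-like cells, and so was the type I interferon list at -0.09, -0.12, -0.07 and 0.04.

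SAA_CsA against healthy asked the same of cyclosporine alone. Genes induced by interferon gamma were higher in all 5 classes read, among them the GTPases Gbp2, Igtp and Iigp1 and, in monocyte-like cells, the T cell attractant Cxcl10. H2-Q7, a nonclassical MHC class I gene, was higher in neutrophil-like, monocyte-like, B progenitor-like and erythroid-like cells. T-like cells had more of the cytotoxic genes Gzma, Gzmk and Ccl4, of the inhibitory receptors Pdcd1 and Lag3 and of mitotic genes, and less of Ccr7, which guides naive T cells to lymph nodes. Monocyte-like cells had less Il1b, Il1rn, Hpgd and Alox5, genes of inflammation and of lipid mediators. Neutrophil-like cells had less of S phase genes and B progenitor-like cells less of G2/M genes.

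In neutrophil-like cells of SAA_CsA, H2-Q7 (chr17:35439155-35443773) stood at 129 v 4.10 CPM (SAA_CsA v healthy; ratio 31.4, 25.7 to 38.7) and Wfdc17 at 395 v 31.4 CPM (12.6, 11.7 to 13.6). Cd3d, a gene of the T cell receptor complex here read in neutrophil-like cells, stood at 33.0 v 203 CPM (0.163, 0.151 to 0.175), and Thbs1 at 22.1 v 128 CPM (0.172, 0.158 to 0.188). Clusters 9, 28 and 36 held 59.6% of the neutrophil-like cells of SAA_CsA and 60.0% of those of SAA_CsA_RvE1, but 4.36% in healthy and 12.1% in SAA_RvE1, where clusters 1, 8, 10 and 21 held most. Wfdc17 and Oasl2 were leading genes of cluster 9, Cstdc5 of cluster 1, and Cd3d and Thbs1 of clusters 10 and 21. With each cluster at the same weight in both libraries, Wfdc17 came to 4.48, Cd3d to 0.362 and Thbs1 to 0.352.

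In monocyte-like cells, Gbp2 stood at 73.4 v 9.14 CPM (8.03, 6.11 to 10.7) and H2-Q7 at 67.9 v 11.1 CPM (6.14, 4.77 to 8.01), while Hpgd stood at 4.43 v 56.8 CPM (0.0781, 0.0532 to 0.111). Lactoferrin (Ltf) stood at 165 v 1128 CPM (0.146, 0.138 to 0.156). Cluster 30 held 19.7% of the monocyte-like cells of healthy and 6.94% of those of SAA_CsA. The Ltf ratio was 0.323 with no cells removed as doublets, 0.437 with at least 1000 UMIs per cell and 0.482 with the clusters at the same weight. B progenitor-like cells had more H2-Q7 (403 v 86.5 CPM; 4.66, 4.21 to 5.18) and Cd74, the MHC class II invariant chain (615 v 249.9 CPM; 2.46, 2.30 to 2.63), and less Pttg1, which encodes securin (62.5 v 153 CPM; 0.409, 0.353 to 0.473). In erythroid-like cells Apol11a, of the apolipoprotein L family, stood at 199.8 v 4.67 CPM (42.8, 32.7 to 56.95) and H2-Q7 at 156.5 v 6.14 CPM (25.5, 20.1 to 32.8); Ryk, a receptor for Wnt ligands, stood at 20.3 v 55.7 CPM (0.364, 0.290 to 0.452).

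Tpm3-rs7 (chr14:113314608-113316754) and Gm10260 (chr13:97760072-97760632), intronless copies of other genes, were lower together in both libraries of mice given cyclosporine. These genes were chosen for a low level in SAA_CsA_RvE1 and a level near healthy in SAA_RvE1, not for their level in SAA_CsA. Their summed level in SAA_CsA was 0.154 of healthy in neutrophil-like cells (0.142 to 0.167), 0.180 in monocyte-like, 0.316 in B progenitor-like, 0.259 in mature B-like, 0.2585 in erythroid-like, 0.0564 in T-like and 0.395 in macrophage-like cells. In SAA_CsA_RvE1 it was 0.0930, 0.0746, 0.0357, 0.1495, 0.0528, 0.0656 and 0.794 (0.507 to 1.202) of healthy in the same order. In SAA_RvE1 it was 0.948 in neutrophil-like, 1.12 in monocyte-like and 1.05 in B progenitor-like cells. Counts of such copies also depend on reads shared with the parent gene: Rps18, the parent of Gm10260, stood at 922, 907, 1306 and 1523 CPM in B progenitor-like cells, and Gm10260 at 582, 616, 178 and 15.8 CPM.

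**Figure D2:**
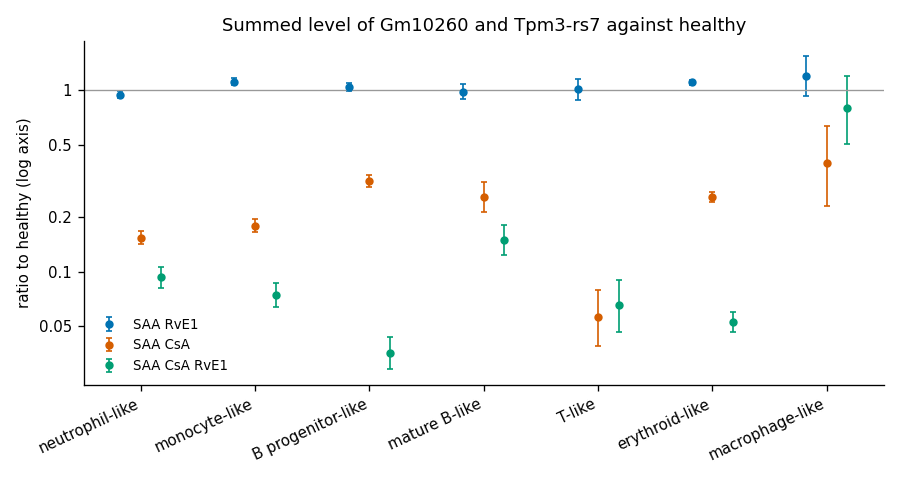
Ratio to healthy (log axis) of the summed CPM of Gm10260 and Tpm3-rs7 in 7 classes, 1 point per SAA library, bars being 95% intervals of the counting error. SAA_RvE1 lay near 1 in each class, while SAA_CsA ran from 0.0564 in T-like to 0.395 in macrophage-like cells. The genes were chosen for being near healthy in SAA_RvE1 and low in SAA_CsA_RvE1, and SAA_CsA did not enter that choice.

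In T-like cells of SAA_CsA (115, against 206 in healthy) the exhaustion list had a median log2 ratio of 4.28 to healthy, or 4.08 with Tox2, without a UMI in healthy, at a floor of 3 UMIs. All 13 genes were higher, with Lag3 at 159 v 2.29 CPM (69.5, 18.7 to 582; 2 UMIs in healthy). Cytotoxic genes had a median of 2.04 with 23 of 23 higher: Ccl4 stood at 508 v 14.9 CPM (34.2, 19.7 to 64.9) and Gzma at 265 v 17.2 CPM (15.4). The naive and memory list stood at -1.63, with Ccr7 at 16.2 v 213 CPM (0.0763), though Bcl2, which keeps T cells alive, was higher (588 v 251 CPM, 2.35). Genes induced through calcineurin and NFAT, the step that cyclosporine blocks, stood at 1.65, with Nr4a2 at 109 v 4.58 CPM (23.8) and Tox at 403 v 33.2 CPM (12.1). Nr4a2 and Tox are members of the exhaustion list too, so the medians of these lists are not independent. G2/M genes stood at 2.17 (16 of 16 higher), S phase genes at 0.65, NF-kB genes at 0.85, oxidative phosphorylation at 0.38 (0.24 with TMM scaling) and ribosomal protein genes at -0.49. The regulatory T list lay at 0.32, at percentile 77.1 of matched random lists, with Foxp3, the factor that defines regulatory T cells, at 6.49 v 52.6 CPM (0.123, 0.0323 to 0.338).

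Among the named genes of T-like cells, Ccr9, a homing receptor for the gut, stood at 3.25 v 89.2 CPM (0.0364, 0.00433 to 0.136; 2 v 78 UMIs) and Ly6c1 at 3.25 v 83.5 CPM (0.0389, 0.00462 to 0.146; 2 v 73 UMIs). The others, Retnlg (1187 v 13.7 CPM; 86.4, 49.2 to 168) and Mmp8 (65 v 0 UMIs; lower bound of the ratio 24.3), are neutrophil genes, and the T-like cells of SAA_CsA and SAA_RvE1 also held S100a8 at 4135 and 3907 CPM, against 214 in healthy and 136 in SAA_CsA_RvE1. With no cells removed as doublets the ratio of Retnlg was 1.73.

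The interferon gamma list had a median log2 ratio in SAA_CsA of 0.53 in neutrophil-like (16 of 16 higher), 0.86 in monocyte-like (25 of 26), 0.55 in B progenitor-like, 0.59 in T-like (30 of 30) and 0.87 in erythroid-like cells. Among its genes were Gbp2 (34.0 v 7.88 CPM, 4.31) and Igtp (2.77) in neutrophil-like cells, Cxcl10 in monocyte-like cells (44.5 v 4.01 CPM; 11.1, 7.38 to 17.4), Nlrc5, the activator of MHC class I genes, in T-like cells (260 v 75.5 CPM, 3.44), and Tgtp2 (20.9 v 5.24 CPM, 3.99) and Psmb9 (76.3 v 22.0 CPM, 3.46) in erythroid-like cells. The type I interferon list stood at 0.61 in neutrophil-like (Zbp1 35.9 v 5.10 CPM, 7.03; Oasl2 76.7 v 11.6 CPM, 6.61), 0.67 in B progenitor-like (Isg15 26.4 v 5.59 CPM, 4.72), 0.60 in T-like and 0.75 in erythroid-like cells (Oasl2 62.7 v 3.03 CPM, 20.7), but at -0.06 in monocyte-like cells (percentile 22.1), where Zbp1 was higher (102 v 45.4 CPM, 2.25) and Ifi44 lower (3.26 v 17.5 CPM, 0.186). With the neutrophil-like clusters at the same weight in both libraries, its median was -0.10 in SAA_CsA and -0.01 in SAA_CsA_RvE1, and that of the interferon gamma list 0.185 and 0.285. Interferon genes were not left out of the clustering, and Oasl2 was a leading gene of cluster 9 and Rtp4 of cluster 36. Equal weights may thus remove part of the interferon difference itself, so they cannot show that the make-up of the class accounts for it. The medians of all genes were -0.19 in neutrophil-like, -0.11 in erythroid-like and 0.13 in T-like cells of SAA_CsA against healthy, so these lists stood apart from their class by more, or in T-like cells less, than their own medians.

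MHC class II genes in SAA_CsA stood at 1.12 in monocyte-like cells, with H2-Eb1 at 78.6 v 32.1 CPM (2.45), and at 0.54 in B progenitor-like cells, where the immature to mature B list stood at 0.43 and NFAT targets at 0.40 (6 of 6 genes higher). Strain alleles, weighed below for the interferon gamma list, were not tested as a source of the MHC class II medians in any comparison. Lower lists in monocyte-like cells were resolvin receptors and lipid mediators at -0.58 (Alox5, the 5-lipoxygenase, 11.7 v 35.6 CPM, 0.330), early response genes at -0.50 and NF-kB genes at -0.47 (Il1b 21.4 v 85.0 CPM, 0.252; Il1rn 0.303; Icam1 higher at 1.60). Cluster 30, with Il1b among its leading genes, held fewer of these cells in SAA_CsA. With the clusters at the same weight the lipid mediator list came to -0.20 and the NF-kB list to -0.23. Neutrophil RNA in these cells, where Ltf stood at 0.146 of healthy, was not tested as a source of either list. Lower lists in neutrophil-like cells were early response genes at -0.71 (Egr1 0.347; Hspa8 246 v 558 CPM, 0.440), S phase genes at -0.56 (Mcm3 0.517), stress response genes at -0.36, NF-kB genes at -0.35 and primary granule genes at -0.31 (Mpo 193 v 298 CPM, 0.648; Elane 640 v 953 CPM, 0.672). The last 3 came to -0.12, -0.10 and -0.07 with TMM scaling. G2/M genes stood at -0.38 in B progenitor-like cells (27 of 27 lower; Ube2c 385 v 671 CPM, 0.573; -0.24 with the clusters at the same weight), stress response genes at -0.31, and ribosomal protein genes at -0.30 in erythroid-like cells (-0.20 with TMM scaling). In this comparison 20 medians of 73 were higher and 13 lower by at least 0.3 log2 beyond their random range. Of these 33, 5 came under 0.3 with TMM scaling and 8 with the clusters at the same weight.

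SAA_CsA_RvE1 against healthy asked how close the marrow came to healthy when both drugs were given. The interferon gamma genes, H2-Q6 and H2-Q7 and the MHC class II genes were higher here too, with Irf1, Gbp2 and Cxcl10 among them. T-like cells had more Pdcd1, Lag3, Gzmk and Ctla4 and the cytokine gene Spp1, with Foxp3 near its healthy level, and less Il6ra and Ccr7. Ly6c1, Cd3d and Ifi202b were lower in myeloid cells, and Ryk in erythroid-like cells.

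H2-Q7 stood at 234.5 v 4.10 CPM in neutrophil-like cells (57.1, 46.8 to 70.5), 144 v 11.1 in monocyte-like cells (13.0, 10.1 to 16.9), 555 v 86.5 in B progenitor-like cells (6.42, 5.82 to 7.09) and 261 v 6.14 in erythroid-like cells (42.5, 33.7 to 54.3). Its close relative H2-Q6 stood at 102 v 10.8 CPM in neutrophil-like cells (9.47, 8.31 to 10.8). Gbp2 stood at 83.5 v 9.14 CPM in monocyte-like cells (9.13, 6.90 to 12.3), Cd74 at 781 v 249.9 CPM in B progenitor-like cells (3.13, 2.94 to 3.33) and Apol11a at 194 v 4.67 CPM in erythroid-like cells (41.6, 31.9 to 55.2). Ly6c1 stood at 12.5 v 195 CPM in neutrophil-like cells (0.0641, 0.0556 to 0.0737) and 30.8 v 512 CPM in monocyte-like cells (0.0601, 0.0503 to 0.0712). Reads can be shared between Ly6c1 and its near copy Ly6c2, which stood at 733, 753, 1288 and 1289 CPM in neutrophil-like cells, so that their sum was 928, 948, 1323 and 1302 CPM. With the neutrophil-like clusters at the same weight, Ly6c1 came to 0.155 and Cd3d, at 22.6 v 203 CPM (0.111, 0.09999 to 0.124), to 0.235. Ifi202b, an interferon-induced gene scarcely expressed in C57BL/6 mice, stood at 4.65 v 74.6 CPM in monocyte-like cells (0.0624, 0.0382 to 0.0965). Tpm3-rs7 was lower in B progenitor-like cells (6.86 v 51.5 CPM; 0.133, 0.0881 to 0.194), and Ryk in erythroid-like cells (7.93 v 55.7 CPM; 0.142, 0.105 to 0.190).

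In the 100 T-like cells of SAA_CsA_RvE1, Spp1 (osteopontin) stood at 269.6 v 1.14 CPM (236, 41.7 to 9364; 1 UMI in healthy) and Pdcd1 at 276 v 3.43 CPM (80.5, 27.1 to 395; 3 UMIs in healthy). Il6ra, the receptor for interleukin 6, stood at 3.39 v 101 CPM (0.0337, 0.00402 to 0.125; 2 v 88 UMIs) and Treml2 at 3.39 v 81.2 CPM (0.0417, 0.00496 to 0.156; 2 v 71 UMIs); with no cells removed as doublets these ratios were 0.246 and 0.208. The exhaustion list stood at 4.41 with 15 of 15 higher, or 3.49 with Tox2 and Havcr2 at the floor. The cytotoxic list stood at 2.18 (Ccl4 46.6; Gzmk 263 v 9.15 CPM, 28.7), NFAT targets at 1.61 (Tnfrsf9 110.2 v 9.15 CPM, 12.04), NF-kB genes at 0.88, oxidative phosphorylation at 0.39 (0.25 with TMM scaling), the naive and memory list at -1.53 (Igfbp4 0.129) and ribosomal protein genes at -0.40. The regulatory T list stood at 1.04, with Ctla4 at 117 v 14.9 CPM (7.87), Tnfrsf4 at 181 v 29.8 CPM (6.10) and Foxp3 at 0.902 of healthy.

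**Figure D3:**
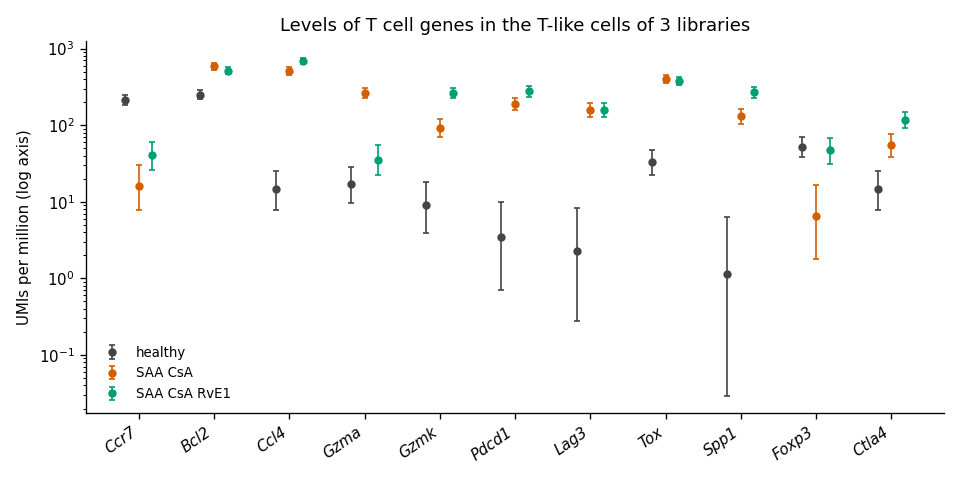
Levels (CPM, log axis) of 11 genes in the T-like cells of healthy, SAA_CsA and SAA_CsA_RvE1, bars being 95% Poisson intervals of the counting error. Pdcd1, Lag3, Ccl4 and Spp1 were higher in both SAA libraries than in healthy, Ccr7 was lower in both, and Foxp3 was lowest in SAA_CsA at 6.49 CPM.

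In SAA_CsA_RvE1 the interferon gamma list stood at 0.78 in neutrophil-like (Gbp2 4.49, Igtp 3.49), 0.82 in monocyte-like (27 of 27 higher; Cxcl10 46.1 CPM, 11.5), 0.64 in B progenitor-like (Nlrc5 67.0 v 18.7 CPM, 3.57), 0.72 in T-like (28 of 30; Gbp6 3.79) and 1.34 in erythroid-like cells (Irf1 18.9 v 1.56 CPM, 12.1; Tgtp2 6.44). The type I interferon list stood at 0.78 (Zbp1 8.25), 0.76 (Isg15 6.10, Rsad2 5.14), 0.79 and 1.02 (Oasl2 28.4, Rtp4 7.62) in neutrophil-like, B progenitor-like, T-like and erythroid-like cells, and at -0.08 in monocyte-like cells. MHC class II genes stood at 2.02 in monocyte-like cells (H2-Eb1 175 v 32.1 CPM, 5.47; Cd74 1558 v 340.5 CPM, 4.57) and at 1.14 in B progenitor-like cells (H2-DMb1 5.54), where the immature to mature B list stood at 0.58 and S phase genes at -0.31. In monocyte-like cells early response genes stood at -0.32 and NFAT targets at 0.32 (4 of 6 genes higher), the latter -0.05 with each cell thinned to 1000 UMIs. In this comparison 19 medians of 73 were higher and 4 lower. Of these 23, 3 came under 0.3 with TMM scaling and 3 with the clusters at the same weight.

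**Figure D4:**
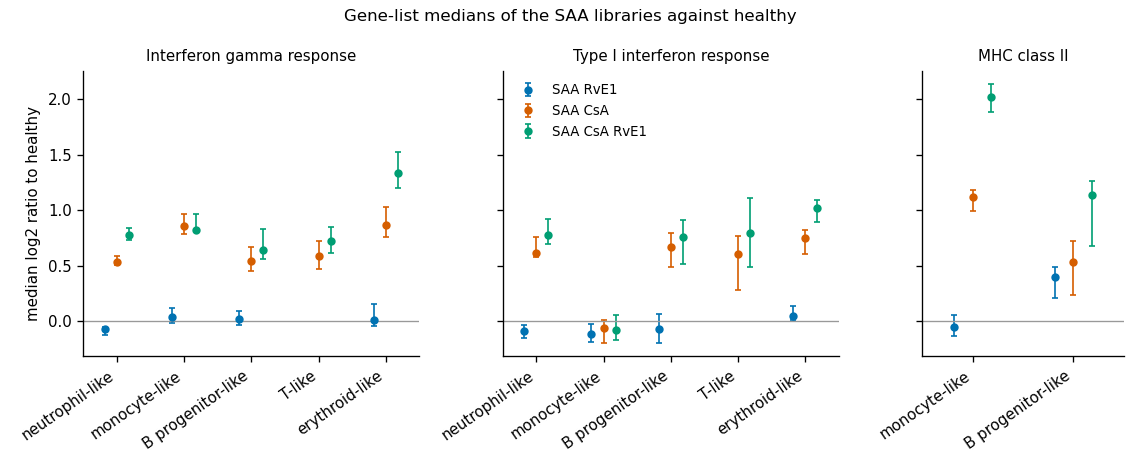
Median log2 ratio to healthy of 3 gene lists in each class read, 1 point per SAA library, bars being 95% intervals of the counting error. The interferon gamma list lay between -0.07 and 0.03 in SAA_RvE1 and between 0.53 and 1.34 in the libraries of mice given cyclosporine.

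SAA_CsA_RvE1 against SAA_CsA asked what resolvin E1 added to cyclosporine. T-like cells with both drugs had more of the regulatory T genes Foxp3, Ctla4 and Tnfrsf18 and less of the mitotic genes, with Gzmk higher and Gzma and Gzmm lower. Monocyte-like cells had more MHC class II genes and more Alox5, Fpr1 and Fpr2, enzyme and receptors of lipid and peptide mediators. They differed in their clusters: cluster 30 held 22.8% of them against 6.94% in SAA_CsA, and cluster 18 29.5% against 38.6%. Neutrophil-like cells had more of the immediate-early genes Egr1, Fosb and Jun and of Tnf. Erythroid-like cells had more interferon gamma genes.

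In T-like cells, Foxp3 stood at 47.5 v 6.49 CPM (SAA_CsA_RvE1 v SAA_CsA; ratio 7.31, 2.56 to 28.7), Tnfrsf18 at 214 v 99.0 CPM (2.16, 1.58 to 2.98), Ctla4 at 117 v 55.2 CPM (2.12) and Spp1 at 269.6 v 129.9 CPM (2.08, 1.58 to 2.75). The regulatory T list stood at 0.91 with 8 of 9 genes higher. S phase genes stood at -0.52 and G2/M genes at -1.66, with Ube2c at 5.09 v 52.0 CPM (0.0979, 0.0192 to 0.313). The exhaustion, cytotoxic and naive lists lay at 0.04, -0.07 and -0.05, though Gzmk stood at 263 v 92.5 CPM (2.84), Gzma at 35.6 v 265 CPM (0.135) and Gzmm at 0.0614. Retnlg (6.78 v 1187 CPM; 0.00571, 0.00155 to 0.0147) and Lyz2 (22.0 v 825 CPM; 0.0267, 0.0141 to 0.0461), both myeloid genes, came to 0.5999 and 0.622 with no cells removed as doublets.

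Neutrophil-like cells had Egr1 at 112 v 36.8 CPM (3.05, 2.82 to 3.29), Fosb at 58.5 v 23.1 CPM (2.53, 2.29 to 2.80), Wfdc17 at 134.7 v 395 CPM (0.341, 0.326 to 0.357) and Ifitm1, an interferon-induced membrane protein, at 197 v 410.2 CPM (0.480, 0.461 to 0.499). NFAT targets stood at 0.78 (4 of 5 genes higher; Tnf 71.0 v 40.1 CPM, 1.77) and early response genes at 0.63 (Jun 239 v 99.8 CPM, 2.40) in these cells. Egr1 is a member of both lists. In monocyte-like cells MHC class II genes stood at 1.03 (H2-Aa 380 v 177 CPM, 2.15), which was -0.04 in cells with a Y-linked UMI alone. NFAT targets stood at 0.41 there (4 of 6 genes higher; Egr1 34.99 v 11.7 CPM, 2.98), -0.04 with cells thinned to 1000 UMIs, and the resolvin receptor and lipid mediator list at 0.38 (Alox5 31.7 v 11.7 CPM, 2.70; Fpr2 60.5 v 29.6 CPM, 2.04). Vcan, a matrix proteoglycan, stood at 123 v 255 CPM (0.483, 0.439 to 0.531) and Ly6c1 at 30.8 v 84.8 CPM (0.363, 0.3002 to 0.437). Ltf (1133 v 165 CPM; 6.86, 6.45 to 7.30) and Ngp (3170 v 673 CPM; 4.71, 4.57 to 4.87), genes of neutrophil granules, turned to 0.322 and 0.429 with no cells removed as doublets. They came to 7.75 and 14.1 with at least 1000 UMIs per cell and to 1.91 and 1.31 with the clusters at the same weight. At the same weight the medians of MHC class II genes, NFAT targets and the lipid mediator list were 0.88, 0.19 and 0.06. Lists were not recomputed with no cells removed as doublets. Fpr1 and Fpr2 were also leading genes of neutrophil-like clusters. Neutrophil RNA in monocyte-like cells was thus not tested as a source of the lipid mediator list.

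B progenitor-like cells with both drugs had more of the mitotic genes Ube2c (617 v 385 CPM; 1.60, 1.504 to 1.71) and Cenpf (403 v 266 CPM; 1.51, 1.40 to 1.64), less Myl10 (33.6 v 59.1 CPM; 0.568, 0.459 to 0.703) and Trib2 (43.9 v 73.4 CPM; 0.598, 0.495 to 0.722), and MHC class II genes at 0.39. Erythroid-like cells had H2-Q7 at 261 v 157 CPM (1.67, 1.53 to 1.82) and H2-Q6 at 68.8 v 40.1 CPM (1.72, 1.44 to 2.05), and the interferon gamma list at 0.44 with 21 of 21 genes higher (Gbp2 19.2 v 3.66 CPM, 5.24), or -0.29 in cells with a Y-linked UMI alone. They had less Chil3, a chitinase-like gene of myeloid cells (59.3 v 183 CPM; 0.324, 0.286 to 0.367; 0.619 with no cells removed as doublets), and less Myb, a factor of early progenitors (62.0 v 107 CPM; 0.580, 0.507 to 0.664). In the other classes the interferon gamma list lay under the limit of 0.3 but above its random range, at 0.22 in neutrophil-like (17 of 18 higher), 0.20 in T-like (22 of 31), 0.11 in B progenitor-like (18 of 26) and 0.05 in monocyte-like cells (19 of 30). In this comparison 8 medians of 73 were higher, 2 lower and 63 lay between -0.23 and 0.30. Of the 10 described, 2 came under 0.3 with the clusters at the same weight.

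SAA_RvE1 against SAA_CsA asked how the drugs differed when each was given alone. Interferon gamma genes were lower with resolvin E1 in all 4 classes read, as were type I interferon genes in 3 of them, with Gbp2, Cxcl9, Cxcl10 and Oasl2 among them. MHC class II genes were lower too, Cd74 in monocyte-like cells among them. Primary granule genes such as Elane and Mpo were higher in neutrophil-like cells, mitotic genes such as Ube2c and Pttg1 in B progenitor-like cells, and Alad, an enzyme of haem synthesis, in erythroid-like cells.

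H2-Q7 stood at 3.79 v 129 CPM in neutrophil-like cells (SAA_RvE1 v SAA_CsA; 0.0295, 0.0237 to 0.0363), 11.6 v 67.9 in monocyte-like cells (0.171, 0.134 to 0.217) and 80.6 v 403 in B progenitor-like cells (0.1998, 0.178 to 0.224). Oasl2 stood at 12.9 v 76.7 CPM in neutrophil-like cells (0.168, 0.149 to 0.189; 0.296 with the clusters at the same weight) and 3.48 v 62.7 CPM in erythroid-like cells (0.0554, 0.0370 to 0.0804). Gbp2 stood at 11.6 v 73.4 CPM in monocyte-like cells (0.158, 0.124 to 0.2004), Apol11a at 9.75 v 199.8 CPM in erythroid-like cells (0.0488, 0.0387 to 0.0609) and Fosb at 30.4 v 93.7 CPM in B progenitor-like cells (0.324, 0.265 to 0.395). Ly6c1 was higher in neutrophil-like cells (194 v 34.5 CPM; 5.63, 5.25 to 6.04; 2.67 with the clusters at the same weight) and monocyte-like cells (523 v 84.8 CPM; 6.17, 5.68 to 6.72), as were Cstdc5 in neutrophil-like cells (257 v 50.1 CPM; 5.13, 4.84 to 5.44; 2.21 at the same weight) and Ifi202b in monocyte-like cells (67.1 v 10.2 CPM; 6.60, 5.18 to 8.50). Ifi30, a thiol reductase of antigen processing (288 v 135 CPM; 2.13, 1.93 to 2.37), and Pttg1 (139 v 62.5 CPM; 2.22, 1.91 to 2.59) were higher in B progenitor-like cells. Alad (1595 v 702 CPM; 2.27, 2.19 to 2.36) was higher in erythroid-like cells.

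The interferon gamma list stood at -0.64, -0.998, -0.59 and -0.91 in neutrophil-like, monocyte-like, B progenitor-like and erythroid-like cells, with Cxcl9 at 0.120 and Cxcl10 at 0.141 of SAA_CsA in monocyte-like cells. The type I interferon list stood at -0.90, -0.72 and -0.59 in neutrophil-like, B progenitor-like and erythroid-like cells, and MHC class II genes at -1.17 in monocyte-like (Cd74 224 v 762 CPM, 0.294) and -0.32 in B progenitor-like cells. NFAT targets stood at -0.54 in B progenitor-like cells (5 of 6 genes lower). Higher lists were primary granule genes at 0.47 in neutrophil-like cells (Elane 1166 v 640 CPM, 1.82; Prtn3 1.52; Mpo 1.51), G2/M genes at 0.43 in B progenitor-like cells (27 of 27 higher; Ube2c 704 v 385 CPM, 1.83; Cdc20 1.67), ribosomal protein genes at 0.37 in erythroid-like cells and the resolvin receptor and lipid mediator list at 0.30 in monocyte-like cells (Alox5 2.74, Fpr1 2.48). Neutrophil RNA in monocyte-like cells was not tested as a source of the lipid mediator list. The other 42 medians of 56 lay between -0.28 and 0.30. Of the 14 described, 1 came under 0.3 with TMM scaling and 3 with the clusters at the same weight.

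SAA_CsA_RvE1 against SAA_RvE1 asked what cyclosporine added to resolvin E1. Interferon gamma genes were higher with both drugs in all 4 classes read, as were type I interferon genes in 3 of them, among them Gbp2, Igtp, Tap1, Oasl2, Zbp1 and Irf1. MHC class II genes, H2-Q6 and H2-Q7 were higher in the classes named below, and NFAT targets in neutrophil-like and B progenitor-like cells. Nlrc5 was higher in B progenitor-like cells. Ly6c1, Cd3d and Ifi202b were lower in myeloid cells, Pttg1 and Ifi30 in B progenitor-like cells and Alad in erythroid-like cells.

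H2-Q7 was 61.9 times as high in neutrophil-like cells (50.2 to 77.0), 12.4 times in monocyte-like cells (9.81 to 15.8), 6.89 times in B progenitor-like cells (6.19 to 7.70) and 25.6 times in erythroid-like cells (20.7 to 32.0). H2-Q6 stood at 102 v 13.4 CPM in neutrophil-like cells (7.64, 6.77 to 8.63), Cd74 at 1558 v 224 CPM in monocyte-like cells (6.95, 6.57 to 7.35), Nlrc5 at 67.0 v 17.3 CPM in B progenitor-like cells (3.87, 3.02 to 5.01) and Oasl2 at 86.1 v 3.48 CPM in erythroid-like cells (24.8, 17.3 to 36.8). Ly6c1 stood at 0.0644 of SAA_RvE1 in neutrophil-like cells (0.0558 to 0.0739; 0.144 with the clusters at the same weight) and 0.0588 in monocyte-like cells (0.0493 to 0.0697), Cd3d at 0.134 (0.120 to 0.149) and Ifi202b at 0.0693 (0.0425 to 0.107). Pttg1 (40.7 v 139 CPM; 0.293, 0.247 to 0.346) and Ifi30 (94.6 v 288 CPM; 0.329, 0.294 to 0.367) were lower in B progenitor-like cells, as was Alad (687.5 v 1595 CPM; 0.431, 0.417 to 0.446) in erythroid-like cells.

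Interferon gamma genes stood at 0.96 in neutrophil-like (Gbp2 5.41, Igtp 4.25, Tap1 3.41), 1.03 in monocyte-like (Cxcl10 7.37), 0.71 in B progenitor-like and 1.30 in erythroid-like cells (Irf1 9.35). The type I interferon list stood at 0.98 in neutrophil-like (Oasl2 6.29, Zbp1 6.05), 0.87 in B progenitor-like and 0.72 in erythroid-like cells, but at 0.03 in monocyte-like cells (percentile 76.7). MHC class II genes stood at 2.11 in monocyte-like (H2-Eb1 5.14) and 0.72 in B progenitor-like cells. NFAT targets stood at 0.66 in neutrophil-like (5 of 5 genes higher), 0.34 in B progenitor-like (5 of 6) and 0.32 in monocyte-like cells (3 of 6), the immature to mature B list at 0.49, and early response genes at 0.34 in neutrophil-like and 0.37 in B progenitor-like cells. No list was lower by 0.3 log2 beyond its random range, and the other 41 medians of 56 lay between -0.27 and 0.21. Of the 15 higher ones, 3 came under 0.3 with the clusters at the same weight.

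The genes of the drugs' targets were read in every class. Ltb4r1, a receptor for leukotriene B4 and resolvin E1, stood at 304 (297 to 311), 346 (339 to 354), 281 (274 to 287) and 282 (274 to 290) CPM in neutrophil-like cells and at 120.8, 120.9, 84.2 and 100.1 CPM in monocyte-like cells. Cmklr1, the other receptor of resolvin E1, had 4, 3, 10 and 4 UMIs in all monocyte-like cells and 3, 2, 0 and 2 in all macrophage-like cells. Ppia, which encodes cyclophilin A, the protein that cyclosporine binds, stood at 2896, 2847, 2526 and 2511 CPM in T-like cells and 1122, 1129, 931 and 1004 CPM in neutrophil-like cells. The calcineurin genes Ppp3ca and Ppp3cb stood at 51.5, 115, 63.3 and 72.9 CPM and at 44.6, 39.3, 97.4 and 66.1 CPM in T-like cells.

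Some lists differed in no comparison by 0.3 log2 beyond their random range. Their medians lay between -0.26 and 0.16 for efferocytosis (12 medians), -0.17 and 0.25 for haem synthesis (6), -0.20 and 0.12 for the pro-B and pre-B stage (6), -0.14 and 0.18 for secondary granules (6), -0.13 and 0.15 for mature neutrophils (6), -0.27 and 0.30 for glycolysis and hypoxia (21), -0.24 and 0.27 for p53 and DNA damage (27) and -0.23 and 0.15 for oxidative stress (21). Within the haem list, Alad stood at 702 v 1363 CPM in SAA_CsA against healthy (0.515, 0.496 to 0.534), while Tfrc, the transferrin receptor, was 1.61 and Slc4a1, the band 3 anion exchanger, 1.56 of healthy. Within the mature neutrophil list, Ifitm1 stood at 162, 410.2 and 197 CPM in the SAA libraries against 75.3 in healthy.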

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

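Marker lists, gene lists, comparisons and most alternatives were fixed before the data were examined. Of the tests in this part, those of cell origin and of sample handling were chosen after the result was seen, and so was the set of 2 genes used in them, whose rule was loosened after a first look. The upper bound in the test of neutrophil-like cells and the comparison with background were added after their values were seen.

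Barcodes over the mitochondrial limit, which the comparisons leave out, were more frequent in SAA_CsA (5.14%, 4.56 to 5.77) and SAA_CsA_RvE1 (5.71%, 5.05 to 6.44) than in healthy (2.71%, 2.40 to 3.06), with 3.33% in SAA_RvE1. Cells with Xist among cells with Xist or a Y-linked UMI, genes left out of every comparison, made up 72.7% (70.9 to 74.5) of SAA_CsA and 61.7% (59.5 to 63.9) of SAA_CsA_RvE1, against 48.1% in healthy and 39.9% in SAA_RvE1, so the pools held female and male cells in different shares.

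Gm10260 and Tpm3-rs7, on chromosomes 13 and 14, were lower in most classes of the libraries of mice given cyclosporine and near healthy with resolvin E1 alone. The rule that chose them asked for at most 0.4 of healthy in SAA_CsA_RvE1 and a level within 1.5-fold of healthy in SAA_RvE1. It was applied in each class tested with at least 20 CPM in healthy, with at least 3 such classes. Their levels in those 2 libraries are thus no evidence, while SAA_CsA did not enter the rule. A difference in mapping that acts on every cell alike would leave these genes independent of each other, yet cells held both at 1.985 times the number given by independence within cluster and depth in SAA_CsA (1.73 to 2.27) and 2.66 times in SAA_CsA_RvE1 (1.99 to 3.49), against 0.989 in healthy; the lowest bound, 1.73, argues against such a difference. For different shares of the sexes, the test fixed beforehand used SAA_CsA_RvE1. The ratio to healthy within a sex was at most 0.09965 there, but the rule had already made it low, so this is no evidence. SAA_CsA, read afterwards, did not enter the rule. Its ratio was 0.215 in cells with Xist and 0.0148 in cells with a Y-linked UMI. Low values in both argue against different shares of the sexes as well. A mixture of 2 kinds of cells had the values it needs, and the kinds may be host cells and cells that grew from the C57BL/6 graft. Pooled mice of another genotype stay open as another source.

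Interferon gamma genes were higher in the libraries of mice given cyclosporine. Different shares of the sexes are argued against, since the list's median over all named cells was at least 0.73 within each sex. Handling that raises early response genes is argued against in neutrophil-like and monocyte-like cells, where these genes stood at -0.71 and -0.50 in SAA_CsA, the opposite direction, and at -0.01 and -0.32 in SAA_CsA_RvE1. Handling of another kind is not tested by this list, and differences of that size may themselves come from handling. In B progenitor-like (0.22 and 0.24), T-like (0.11 and -0.20) and erythroid-like cells (-0.14 and 0.04) handling cannot be told apart from other sources, because the medians lay between the bounds set for the test or their intervals reached past the lower one.

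Strain alleles of graft-derived cells, without a response of the host-type cells (those with at least 2 UMIs of Gm10260 and Tpm3-rs7), were tested on the median of the interferon gamma list to healthy cells chosen the same way. It was 0.10 (0.03 to 0.25) in the 66 host-type monocyte-like cells of SAA_CsA and -0.17 (-0.225 to -0.04) in the 88 host-type B progenitor-like cells. These medians cover the 19 and 20 list members that reached 10 CPM in the cells compared. The whole classes had 0.86 and 0.55, over members chosen by the levels of the whole class. Part of the gap may thus come from the genes measured. Cell origin alone needs such low values in host-type cells, but they do not test how far alleles could raise the other cells. Host-type cells were 18.3% (14.5 to 22.7) and 19.0% (15.5 to 22.9) of these classes, where 11.4% and 2.85% would be background had every cell, at its own depth, held the pair at its lowest level in any class of SAA_CsA with at least 100 cells, that of neutrophil-like cells. A response confined to cells without the pair may give the same values and was not tested. The pair also went with sex in SAA_CsA, at 0.215 of healthy in cells with Xist and 0.0148 in cells with a Y-linked UMI. Host-type cells may thus come mostly from some of the pooled mice, and cell origin cannot be told apart from mouse here. In neutrophil-like cells (122 host-type cells, 0.19, 0.14 to 0.30) and erythroid-like cells (33, 0.32, 0.09 to 0.46; medians of 16330 UMIs v 31276 in healthy; 4.96% of the class, 3.44 to 6.90, with 3.02% as background) a response cannot be told apart from allele differences, because the interval spans both bounds set for the test. For neutrophil-like cells, whose own level sets the background, no background share could be given; in SAA_CsA_RvE1 their median was 0.425 (0.293 to 0.591) in 29 cells. Mature B-like cells, for which the list was not planned, had 0.518 (0.097 to 0.695) in 34 host-type cells of SAA_CsA and -0.062 (-0.393 to 0.227) in 29 of SAA_CsA_RvE1.

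Ndufa1 was lower in neutrophil-like, monocyte-like, B progenitor-like and erythroid-like cells of SAA_RvE1. An X-linked allele of the male mice is argued against, since the level in cells with a Y-linked UMI was 0.964 (0.885 to 1.05) of that in cells with Xist, and so are the shares of the sexes, since the ratio to healthy was at most 0.414 within a sex. An allele carried by both sexes of the 3 pooled mice may remain as a source, untested here, as does an effect of the drug.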

How the results depend on the processing

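The alternatives with T-like cells of few neutrophil UMIs, with cells of 1 sex and without the gene minimum were chosen after the results were seen. Of 1024 recomputed list medians 711 stayed within their counting interval, 306 moved and 7 changed sign; of 510 gene ratios 453, 55 and 2; of 323 shares 197, 126 and 0. For list medians, changes of sign were counted only where the median was described as higher or lower, so those of other medians are among the 711 or the 306. Each library clustered by itself gave no HSPC-like and no natural killer-like cluster in SAA_CsA and SAA_CsA_RvE1, and so no value. Over all 387 list medians, 387 of 3897 recomputed values changed sign, against 7 of 1004 among the 99 medians described as higher or lower. The cause of these movements was not tested.

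Signs of gene ratios and of described medians turned as follows. With no doublet-like cells removed, Ltf and Ngp in monocyte-like cells were 0.322 and 0.429 in SAA_CsA_RvE1 against SAA_CsA. In cells with a Y-linked UMI, MHC class II genes of B progenitor-like cells were -0.24 in SAA_RvE1 against healthy, and in SAA_CsA_RvE1 against SAA_CsA the interferon gamma list of erythroid-like cells was -0.29 and the MHC class II list of monocyte-like cells -0.04. With clusters at the same weight, type I interferon genes of neutrophil-like cells were -0.10 in SAA_CsA and -0.005 in SAA_CsA_RvE1 against healthy. Thinned to 1000 UMIs, NFAT targets of monocyte-like cells were -0.052 in SAA_CsA_RvE1 against healthy and -0.043 against SAA_CsA.

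Shares moved as follows, in %. Neutrophil-like: each library alone, healthy 41.0 and SAA_CsA 49.9; at least 1000 UMIs, SAA_RvE1 42.9 and SAA_CsA 49.9; without erythroid-like cells, 47.9, 51.6, 56.6 and 45.3; no gene minimum, 32.3, 35.6, 43.5 and 30.1. Mature B-like: at least 1000 UMIs, healthy 9.07; no doublet-like cells removed, healthy 10.4, SAA_RvE1 8.66 and SAA_CsA 5.49; resolution 3, healthy 9.23; each library alone, healthy 9.35; without erythroid-like cells, 10.6, 8.53, 5.39 and 10.2; no gene minimum, healthy 7.11, SAA_RvE1 5.88 and SAA_CsA_RvE1 6.81. T-like: without erythroid-like cells, healthy 3.39 and SAA_CsA_RvE1 3.67; no gene minimum, healthy 2.28; each library alone, SAA_RvE1 1.45. HSPC-like: without erythroid-like cells, healthy 1.63.

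The interferon gamma list of monocyte-like cells moved as follows. SAA_CsA against healthy: no minimum level 1.10, 50 CPM 0.69, clusters at the same weight 1.10, Xist cells 1.05, Y cells 0.73. SAA_CsA_RvE1 against healthy: 1.2, 0.77 and 0.96, Xist cells 1.14. SAA_CsA_RvE1 against SAA_CsA: thinned -0.11, Xist cells 0.14. SAA_RvE1 against SAA_CsA: no minimum level -1.28, 50 CPM -0.62, Xist cells -1.13, Y cells -0.82. SAA_CsA_RvE1 against SAA_RvE1: no minimum level 1.34, 50 CPM 0.72, thinned 0.78, Xist cells 1.30.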

Other observations

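The tests of host-type cells named here were chosen after the result was seen. Among the mature B-like cells of healthy, 44.2% held at least 2 UMIs of Gm10260 and Tpm3-rs7, against 16.8% in SAA_CsA (background 0.630%) and 10.4% in SAA_CsA_RvE1 (background 0.444%). H2-Q7, which encodes a Qa-2 antigen whose level differs between inbred strains, ran the other way: cells with one of the pair held H2-Q7 at 0.703 times the number given by independence in SAA_CsA and 0.728 times in SAA_CsA_RvE1, against 0.989 in healthy. In host-type cells of SAA_CsA, H2-Q7 stood at 1.87 times the healthy level in monocyte-like, 1.31 in B progenitor-like, 1.755 in mature B-like and 1.83 in erythroid-like cells. In neutrophil-like cells, whose host-type cells could not be set against a background, it stood at 15.05 times.

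The summed level of these genes also went with sex, in opposite ways in SAA_CsA and SAA_CsA_RvE1. In the former it was 0.215 of healthy in cells with Xist and 0.0148 in cells with a Y-linked UMI, while in the latter it was 0.0103 and 0.09965. A candidate explanation is that mice of the same pool differed in their share of host-type cells. The joint excess of 1.985 does not test this, since a mixture within each mouse gives it as well, and mice were not separated within a pool. If so, part of any difference between SAA_CsA and SAA_CsA_RvE1 may come from which mice were pooled, and MHC class II genes of monocyte-like cells, at 1.03 between them, stood at -0.04 in cells with a Y-linked UMI.

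T-like cells of SAA_CsA and SAA_CsA_RvE1 shared high Pdcd1, Lag3, Tox and Ccl4 and differed in Gzmk, Gzma, Foxp3 and the mitotic genes. Their set-gene level was 0.0564 and 0.0656 of healthy. That was the lowest of the classes read in SAA_CsA, but in SAA_CsA_RvE1 B progenitor-like (0.0357) and erythroid-like cells (0.0528) stood lower. So did neutrophil progenitor-like (0.01925), basophil- and mast-like (0.0411) and HSPC-like cells (0.0035, with 2 UMIs in 18 cells) of SAA_CsA_RvE1. Donor T cells of the splenocyte graft are a candidate source that was not tested, since the mixture value of 1.985 covers all cells of SAA_CsA. NFAT targets stood above healthy in both, weeks after the last dose of the calcineurin inhibitor. The NFAT list shares Tox and Nr4a2 with the exhaustion list, so it is not a separate sign of calcineurin activity.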
